A study of Homo sapiens with 6 samples.

How the data were processed

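RNA from A2780 cells was measured in 6 libraries, 3 transfected with a control siRNA and 3 with an siRNA against PART1, all taken 48 h after transfection. Groups and replicate numbers come from the sample titles, and each column of the deposited table was matched to its sample by that title. The deposited values are raw counts per Ensembl gene, not normalized: whole numbers with a different total in each library, from 31641235 to 39672805. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit. Reads were aligned with HISAT2 2.0.5 and counted by the authors with featureCounts 1.5.0-p3 on hg38, per the submitters' processing notes. The annotation release, the strand setting, and how reads shared by several genes were counted are not given in the sources used here. Without a strand setting, reads of overlapping genes on opposite strands cannot be told apart, and the loss of shared reads can lower genes with close copies.

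The table holds 24829 genes, and every gene in it has a count above 0 in at least 4 of the 6 libraries. Symbols were taken from a table of gene names, which matched 24823 of the IDs. Coordinates, gene types, 3' UTRs and exon overlaps come from GENCODE 29 on GRCh38, which is the same assembly as hg38. PART1 and mitochondrially encoded genes were not analysed here, so the planned value for PART1 and the planned fit without mitochondrial genes were not run.

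Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total count 15, by group), which left 18196 genes, and libraries were scaled by TMM (factors 0.986 to 1.01). A quasi-likelihood F-test (glmQLFit and glmQLFTest) of si-PART1 against si-NC used an intercept and the siRNA as terms. P-values are two-sided and Benjamini-Hochberg adjusted over all tested genes, and a gene is said to have risen or fallen where its adjusted p is under 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of its F value. CPM are counts scaled by the TMM library total and are given as mean and SD over the 3 libraries of a group. At these depths the common biological coefficient of variation was 0.0781. Replicates within a group differed by more than sampling noise (chi-square per degree of freedom from 5.33 to 9.98 over genes with at least 20 counts in a pair), so no library is a copy of another.

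Before the data were examined, 40 gene lists were fixed, of which 38 had tested members. Each list was tested with camera of limma 3.58.1 with a preset correlation of 0.01, then with an estimated correlation, and with fry, and p-values were adjusted over lists. The rule for named genes was also fixed then. It takes the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 2 log2 CPM, groups that do not overlap, and a symbol that is not a clone or locus name. It adds up to 4 members with the smallest p from each list, of which the text leaves some out, some of them because they are not reported here, and marker lists are given by their counts and most abundant members. Genes named outside this rule, REST and the REST targets and brain markers among them, are said to be chosen after their values were seen.

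Alternatives were RLE and upper-quartile scaling, no filter on low counts, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, the block with a correction for GC content and length (generalized additive models, mgcv 1.9.3, on the 95.9% of tested genes with both values), and each library left out in turn. The correction without the block was added after the data were seen. All splits of the 6 libraries into 2 groups of 3 were also fitted.

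For the closing section, the longest 3' UTR of each protein-coding gene was taken from GENCODE 29 basic transcripts with a stop codon. Among 11031 tested genes with such a 3' UTR and a mean above 1 log2 CPM, the difference in log2 fold change between genes with and without each word of 7 bases was estimated by least squares. The fit held 3' UTR length, GC content and expression as terms with their squares, cubes and products, and gave a z for each of 16379 words held by at least 20 genes. This step used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.

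The scripts were tested on simulated data. Counts drawn from the real means, library sizes and dispersions of the si-PART1 and si-NC comparison, with 100 genes changed by 0.5 and 100 by 1 on the log2 scale, gave 65 and 88 genes recovered by edgeR among 18024 tested, with 5 false calls. A list of 40 genes shifted by 0.2 on the log2 scale was found by camera in that simulation, and of 20 unshifted lists none passed. Genes were drawn independently there, so false calls of lists whose members vary together were not tested. A word planted with a difference of -0.15 among 11013 simulated genes ranked first in 10 of 10 runs, with a mean estimate of -0.15.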

Results

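The data were gene counts from RNA sequencing of A2780 cells, an established line derived from an ovarian endometrioid adenocarcinoma. Cells received either a negative control siRNA (si-NC) or an siRNA against the long non-coding RNA PART1 (si-PART1), and RNA was taken 48 h after transfection. Each of the 2 groups had 3 libraries. The libraries of si-NC held 31641235, 36352734 and 31993806 counts, and those of si-PART1 35748532, 39672805 and 35411923 counts, in the order of their numbers 1 to 3. The 10 most abundant genes took between 3.74% and 3.85% of the counts of a library. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. PART1 itself was not analysed here, so the depth of the knockdown is not given and the groups rest on the labels.

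The study asked what PART1 does in the response of ovarian cancer cells to inhibitors of poly(ADP-ribose) polymerase (PARP), and compared cells with and without the siRNA. Among the genes with the largest rises after si-PART1 were several with known roles at synapses or in neurons. CHRNB2, a subunit of neuronal nicotinic acetylcholine receptors, rose 8.96-fold, and the neuronal adaptor subunit AP3B2 rose 5.81-fold. The largest falls included LYSET, which acts in the sorting of lysosomal enzymes, at 30.8% of the si-NC level. SLC7A2, a transporter of cationic amino acids, and EIF2D, a translation initiation factor, were each at 36.7%. Most changes were smaller: the median gene that rose did so 1.22-fold, and the median gene that fell stood at 78.6% of its si-NC level.

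In all, 1236 of the 18196 tested genes rose and 1000 fell with si-PART1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 74 rose and 70 fell at least 2-fold. The groups did not overlap for 27.7% of the tested genes, where chance gives 10%. The first principal component, with 29.3% of the variance, separated the groups. The second, with 19.7%, placed si-PART1 library 1 (37.1) and si-PART1 library 3 (-35.6) at opposite ends. By chi-square per degree of freedom, si-PART1 library 3 stood apart in its group. Its pairs with libraries 1 and 2 gave 9.98 and 9.13, while libraries 1 and 2 gave 5.33. With upper-quartile scaling 1007 genes rose and 1242 fell, so that 44.8% of the changed genes were higher, against 55.3% with the main scaling. Without si-NC library 3 the counts were 809 and 619, without si-NC library 2 the count of genes that fell was 612 and that of at least 2-fold falls 43, and DESeq2 put 47 rises and 45 falls at 2-fold or more.

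**Figure D1:**
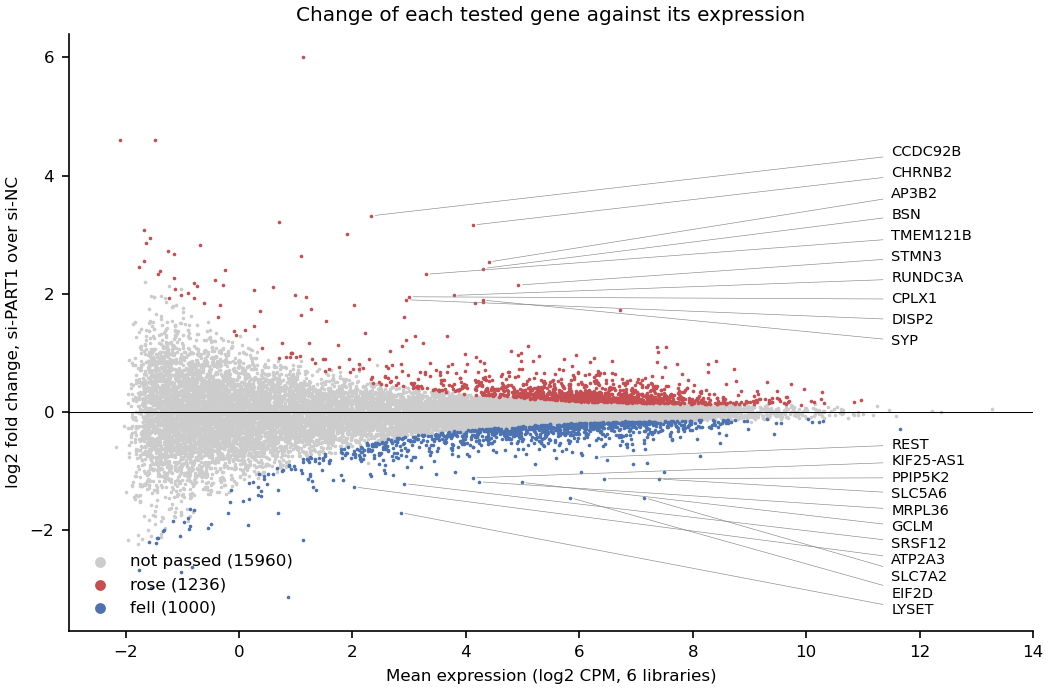
log2 fold change of each tested gene (si-PART1 over si-NC) against its mean expression in log2 CPM (counts scaled by library total) over the 6 libraries; red points rose, blue points fell and grey points did not pass. The 1236 genes that rose and the 1000 that fell reach the smallest folds where expression is highest, and the labelled genes are the 10 largest rises and 10 largest falls by the rule for named genes, with REST, chosen after its values were seen.

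CHRNB2 (ENSG00000160716, chromosome 1, 154567781 to 154580026, hg38) went from 3.46 ± 0.377 CPM in si-NC to 31.0 ± 4.34 CPM in si-PART1 (SD, n = 3 each), a log2 fold change of 3.16 ± 0.12 (SE, edgeR adjusted p = 2.17e-17). AP3B2 (ENSG00000103723, chromosome 15, 82659281 to 82709914) went from 6.16 ± 0.321 to 35.8 ± 2.27 CPM. BSN, a scaffold protein of the presynaptic active zone, rose 5.38-fold, and CPLX1, a complexin that acts in vesicle fusion, rose 3.87-fold. The synaptic vesicle protein SYP rose 3.72-fold, from 8.24 ± 1.69 to 30.7 ± 1.92 CPM. STMN3, of the stathmin family of microtubule regulators, rose 4.44-fold. The rule for named genes, with its mean of at least 2 log2 CPM, also took TMEM121B (5.03-fold), RUNDC3A (3.93-fold) and DISP2 (3.73-fold). CCDC92B (ENSG00000277200, chromosome 17, 2720801 to 2723947, annotated as a long intergenic RNA in GENCODE 29) rose most of the genes taken by that rule, 9.99-fold, but from only 0.891 ± 0.156 CPM. Less abundant genes could rise more. SCG3, a REST target chosen after its values were seen, rose 64.6-fold, from 0.0611 to 4.09 CPM.

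Among the falls, SLC7A2 (ENSG00000003989, chromosome 8, 17497088 to 17570573) went from 207 ± 3.33 CPM in si-NC to 75.9 ± 5.58 CPM in si-PART1 (SD, n = 3 each), a log2 fold change of -1.45 ± 0.05 (SE, edgeR adjusted p = 1.31e-17). EIF2D (ENSG00000143486, chromosome 1, 206571292 to 206612463) went from 83.7 ± 3.38 to 30.7 ± 3.97 CPM. GCLM, the modifier subunit of the enzyme that starts glutathione synthesis, went from 44.2 ± 3.54 to 19.4 ± 1.72 CPM. SLC5A6, a transporter of biotin and pantothenate, fell to 45.6% of its si-NC level, and PPIP5K2, a kinase that makes inositol pyrophosphates, to 45.7%. MRPL36, a protein of the mitochondrial ribosome, fell to 44.2%. ATP2A3, a calcium pump of the endoplasmic reticulum, stood at 41.6%, SRSF12, a splicing regulator, at 43.3%, and the antisense transcript KIF25-AS1 at 46.2%. All 20 of these rises and falls passed the same test in each of the 15 alternative fits. Exons of 8 of the 20 genes overlap exons of another gene in GENCODE 29, most of all LYSET with 22.3% of its exon bases. For LYSET the other gene, AL110118.2, lies on the same strand, so no strand setting would separate their reads. For the rest of the 8 it lies on the opposite strand, and the strand setting of the counting is not given in the sources used here. Reads of those 8 could therefore belong in part to the other gene.

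**Figure D2:**
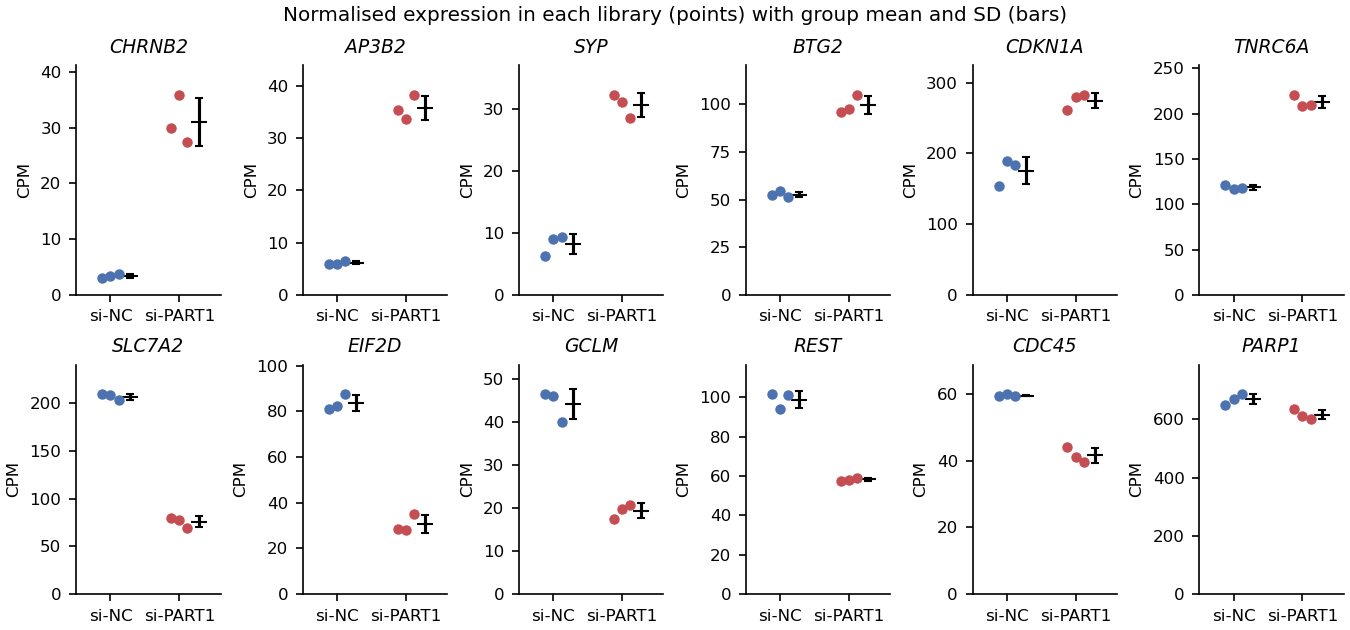
CPM of 12 genes in each library (blue points si-NC, red points si-PART1), with black marks for the mean and SD of the 3 libraries of a group; each axis starts at 0. For CHRNB2, from 3.46 to 31.0 CPM on average, SLC7A2, from 207 to 75.9 CPM, and REST, from 98.8 to 58.2 CPM, the libraries of one group lie apart from those of the other.

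Genes of the DNA repair routes that bear on the response to PARP inhibitors mostly did not pass the test. In the list of homologous recombination genes, 4 of 46 tested members fell and 1 rose (3 and 1 adjusted over the list alone). RAD54L, a DNA translocase that acts in strand exchange, fell to a log2 fold change of -0.31 ± 0.07 (SE, edgeR adjusted p = 0.00242), from 47.3 ± 1.5 to 38.2 ± 0.474 CPM (SD, n = 3 each). RMI1 (-0.32), RAD51C (-0.22) and SWI5 (-0.41, named after its values were seen) also fell, and SHLD2, a shieldin subunit, rose by 0.20 on the log2 scale. PARP1 itself had a log2 fold change of -0.12 ± 0.04 (SE, edgeR adjusted p = 0.0534), from 668 ± 17.7 to 615 ± 16.2 CPM, and its adjusted p ranged from 0.0109 to 0.264 over the 15 alternative fits, 7 of which it passed (without si-PART1 library 1, adjusted p = 0.0418). The call of RAD54L held without any 1 library, but single libraries ended the others: that of RMI1 without si-NC library 2 (adjusted p = 0.0812) or si-PART1 library 2 (0.0508), that of SHLD2 without si-NC library 2 (0.0859), si-NC library 3 (0.162) or si-PART1 library 1 (0.139), that of RAD51C without any library but si-PART1 library 3 (from 0.0614 to 0.148), and that of SWI5 without any but si-NC library 1 and si-PART1 library 2 (from 0.0578 to 0.278). SWI5 also did not pass with limma-voom (adjusted p = 0.0700) or with a correction for GC content and length (0.0965). With that correction, or with the replicate block, 2 members of the list rose.

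Among 24 genes of PARP signalling and base excision repair, the glycosylase MPG was the single one that fell (-0.27; 1 adjusted over the list alone). Of 25 Fanconi anaemia pathway genes 1 rose, REV3L, the catalytic subunit of a translesion polymerase, from 65.4 ± 1.53 to 93.3 ± 4.16 CPM (SD, n = 3 each; 2 higher and 4 lower adjusted over the list alone). Of 19 end joining genes 2 fell, among them APTX (-0.34), which trims damaged DNA ends, and 1, RIF1 (0.15), rose, with the same counts, 2 and 1, adjusted over the list alone. GTF2H3 (-0.22) was the 1 member that fell of 22 genes of nucleotide excision and mismatch repair, and none passed adjusted over the list alone. In the list of replication stress and checkpoint genes, H2AX (-0.23), HLTF (-0.36) and RAD9A (-0.30) fell, and WEE1, the kinase that restrains CDK1, rose by 0.33 on the log2 scale, out of 26 members (3 lower and 2 higher adjusted over the list alone). None of these 6 lists passed camera with the preset correlation, the lowest adjusted p being 0.399 for the checkpoint list. Without si-PART1 library 2, 2 Fanconi anaemia genes and 2 checkpoint genes rose, and the Fanconi anaemia genes that fell numbered 1, 1 and 2 without si-NC library 2, si-PART1 library 2 and si-PART1 library 3. Under other settings 4 Fanconi anaemia genes fell with upper-quartile scaling or the replicate block, 3 with DESeq2 or a correction for GC content and length, and 2 with the stricter filter. Of the checkpoint genes 2 rose with RLE scaling, the stricter filter, DESeq2, the block or the GC and length correction. In the PARP and base excision list 2 fell without si-PART1 library 1, with upper-quartile scaling, DESeq2, limma-voom or the block, and in the excision and mismatch repair list 2 fell with the GC and length correction. The calls of MPG, RIF1, RAD9A and H2AX ended with a correction for GC content and length (adjusted p = 0.159, 0.519, 0.0952 and 0.0681), and that of RIF1 also with upper-quartile scaling (0.0839). Leaving out 1 library ended the call of MPG for si-NC libraries 1, 2 and 3 and si-PART1 library 3 (adjusted p from 0.0610 to 0.0948), that of RIF1 for each but si-NC library 1 (0.0546 to 0.211), that of GTF2H3 for si-NC libraries 1 and 2 and si-PART1 library 2 (0.139, 0.12 and 0.253), and that of RAD9A for each but si-PART1 libraries 2 and 3 (0.0641 to 0.273).

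The targets of the tumour suppressor p53 rose as a group. Of 36 tested p53 targets 18 rose and the other 18 did not pass (25 higher adjusted over the list alone), with a median log2 fold change of 0.23. BTG2, an antiproliferative gene, rose by 0.92 ± 0.06 on the log2 scale (SE, edgeR adjusted p = 1.21e-12), from 52.6 ± 1.43 to 99.4 ± 4.63 CPM (SD, n = 3 each). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose 1.56-fold, from 176 ± 19.4 to 274 ± 10.9 CPM. ZMAT3 rose 1.57-fold, and MDM2, the ubiquitin ligase of p53, rose 1.34-fold. The group passed camera with the preset correlation (adjusted p = 1.32e-14) and with an estimated correlation (adjusted p = 0.0284).

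Of 44 tested genes of DNA replication 20 fell and 23 did not pass (23 lower and 2 higher adjusted over the list alone), and the 1 that rose was E2F7, a repressor of E2F target genes, at a log2 fold change of 0.53. CDC45, a part of the replicative helicase, had a log2 fold change of -0.52, from 59.5 ± 0.285 to 41.7 ± 2.27 CPM (SD, n = 3 each). UHRF1, which maintains DNA methylation at the fork, fell to 80.2%, and thymidine kinase TK1 to 79.1%. Without si-NC library 1, si-NC library 3 or si-PART1 library 2, 12, 10 and 10 members fell, and 2 rose without si-PART1 library 3, with the replicate block and with a correction for GC content and length. The group passed camera with the preset correlation (adjusted p = 2.41e-07) but not with an estimated one (adjusted p = 0.214 with an estimated correlation). Among 45 mitosis genes 7 fell and 1 rose (9 and 1 adjusted over the list alone): the survivin gene BIRC5 (-0.29), CDC20 (-0.31) and AURKB (-0.27) were lower and the kinesin KIF23 (0.25) was higher. The mitosis list passed with the preset correlation (adjusted p = 0.000713), with adjusted p = 0.583 with an estimated correlation, and 3 of its members fell without si-NC library 1, si-NC library 3 or si-PART1 library 2, against 11 without si-PART1 library 3, 15 with a correction for GC content and length, and 16 with the replicate block as well.

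Genes of the small RNA machinery, through which siRNAs and microRNAs act, were higher with si-PART1 as a list. Of 15 tested members 6 rose (7 adjusted over the list alone). TNRC6A, a scaffold of the silencing complex, rose 1.79-fold, from 119 ± 2.58 to 212 ± 6.80 CPM (SD, n = 3 each), a log2 fold change of 0.84 ± 0.05 (SE, edgeR adjusted p = 1.31e-13). The Argonaute genes AGO1 (0.48), AGO2 (0.38) and AGO4 (0.55) rose as well. The list passed camera with the preset correlation (adjusted p = 7.31e-08) and with an estimated correlation (adjusted p = 0.0413). Of 34 interferon-stimulated genes, the usual response to foreign RNA, 2 rose (among them HLA-C, 0.19) and 4 fell (IFITM2, -0.21, BST2, -0.57, and, named after their values were seen, IFITM3, -0.17, and IFI6, -0.63; 3 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.583). The calls of these 5 named genes were lost without some libraries: HLA-C without si-NC library 1 or si-PART1 library 2 (adjusted p = 0.0511 and 0.0545), BST2 without si-NC library 1 or si-PART1 library 3 (0.0703 and 0.05004), IFITM2 without si-NC libraries 1 or 2 or si-PART1 library 1 (0.0556 to 0.0759), IFITM3 without any si-NC library or si-PART1 library 1 (0.0587 to 0.113), and IFI6 without si-NC libraries 2 or 3 or si-PART1 libraries 1 or 2 (0.0619 to 0.117). A correction for GC content and length also ended the calls of IFITM2 (adjusted p = 0.0664) and IFITM3 (0.131), and 2 members of the list fell with it.

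**Figure D3:**
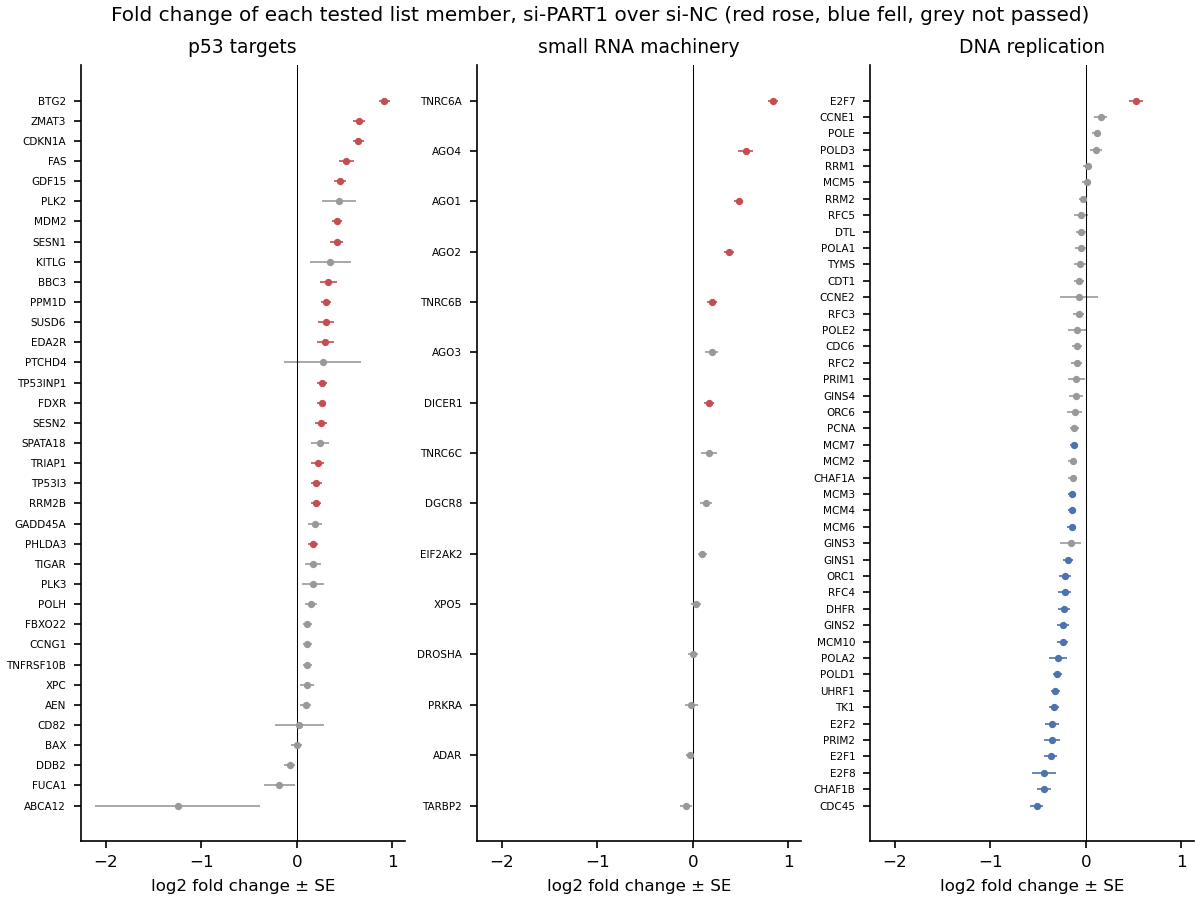
log2 fold change (si-PART1 over si-NC) with its SE for each tested member of 3 fixed lists; red members rose, blue members fell and grey members did not pass. Members that passed lie to the right of 0 for p53 targets (18 of 36) and the small RNA machinery (6 of 15), and mostly to the left for DNA replication (20 of 44 fell).

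Lysosomal and autophagy genes rose: 16 of 43 tested members were higher (21 higher and 1 lower adjusted over the list alone). The protective protein CTSA rose by 0.40 on the log2 scale, the saposin precursor PSAP by 0.22 and the cholesterol exporter NPC1 by 0.33. The list passed camera with the preset correlation (adjusted p = 2.41e-07) and with an estimated correlation (adjusted p = 0.0413). Among 33 mesenchymal and matrix genes 14 rose (9 without si-NC library 3) and 2 fell, THY1 and COL1A1, named after their values were seen (the same counts adjusted over the list alone). The fibronectin receptor subunit ITGA5 rose 1.45-fold and the collagen gene COL1A2 1.28-fold. COL1A1 (-0.32) lost its call without any library but si-PART1 library 1 (adjusted p from 0.0903 to 0.168), and with limma-voom (0.0558) or no filter (0.0591). That list passed with the preset correlation (adjusted p = 3.68e-05), with adjusted p = 0.0579 with an estimated correlation. The list of MAPK and immediate early genes, of which 12 of 29 rose and 1 fell (15 and 1 adjusted over the list alone), passed with the preset correlation (adjusted p = 5.61e-05), with adjusted p = 0.0579 with an estimated correlation. KLF2 (2.43-fold), EGR1 (1.41-fold), EGR3 (1.46-fold) and SPRY4 (1.19-fold) were higher, and 6 rose without si-NC library 1, 7 without si-PART1 library 2 and 7 with upper-quartile scaling. The 1 that fell was ETV4 (-0.25, named after its values were seen; adjusted p = 0.0549 without si-NC library 1).

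Of 19 targets of TGF-beta and BMP signalling 7 rose and 2 fell (10 and 3 adjusted over the list alone), with ID1 (0.27) and CCN2 (0.40) higher and ID4 (-0.23) and SMAD9 (-0.34) lower. SMAD9, named after its values were seen, did not pass without si-NC library 1 or si-PART1 library 2 (adjusted p = 0.0567 and 0.0553). The list passed with the preset correlation (adjusted p = 0.00594), with adjusted p = 0.358 with an estimated correlation. Of 22 YAP targets 6 rose (6 higher and 1 lower adjusted over the list alone), among them PTPN14 and AXL, each by 0.33 on the log2 scale (camera adjusted p = 0.0346, and adjusted p = 0.583 with an estimated correlation). That list no longer passed with upper-quartile scaling (adjusted p = 0.0681), with a correction for GC content and length (adjusted p = 0.12), or without si-NC library 1 (0.152), si-PART1 library 1 (0.134) or si-PART1 library 2 (0.0731, where 1 member fell). With upper-quartile scaling or the replicate block 1 YAP target fell, and with the GC and length correction 2.

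Some genes of oxidative phosphorylation and of the cytosolic ribosome fell, most by small amounts. Of 62 nuclear genes of oxidative phosphorylation 14 fell (23 adjusted over the list alone), with a median of -0.13 on the log2 scale. NDUFA8 of complex I fell to 71.8% of its si-NC level, UQCRFS1 and CYC1 of complex III to 79.1% and 83.1%, and the ATP synthase subunit ATP5MC3 to 83.2%. The list passed camera with the preset correlation (adjusted p = 2.34e-07), with adjusted p = 0.583 with an estimated correlation. Without si-NC library 3, si-PART1 library 1 or si-PART1 library 2, 5, 6 and 9 members fell, and without si-PART1 library 3, 32. With the replicate block 23 fell. Of 76 cytosolic ribosomal protein genes 8 fell (7 adjusted over the list alone), with a median of -0.08. RPS26 fell to 69.6% of its si-NC level, and reads of ribosomal protein genes are uncertain because of their many processed pseudogenes. That list passed with the preset correlation (adjusted p = 5.61e-05), with adjusted p = 0.735 with an estimated correlation, and did not pass without si-PART1 library 1 (adjusted p = 0.0559). Its count of genes that fell was 2, 1, 1, 4 and 31 without si-NC library 2, si-NC library 3 and si-PART1 libraries 1, 2 and 3. It was 13 with upper-quartile scaling, 24 with the replicate block, 14 with the block and a correction for GC content and length, and 4 with that correction alone.

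**Figure D4:**
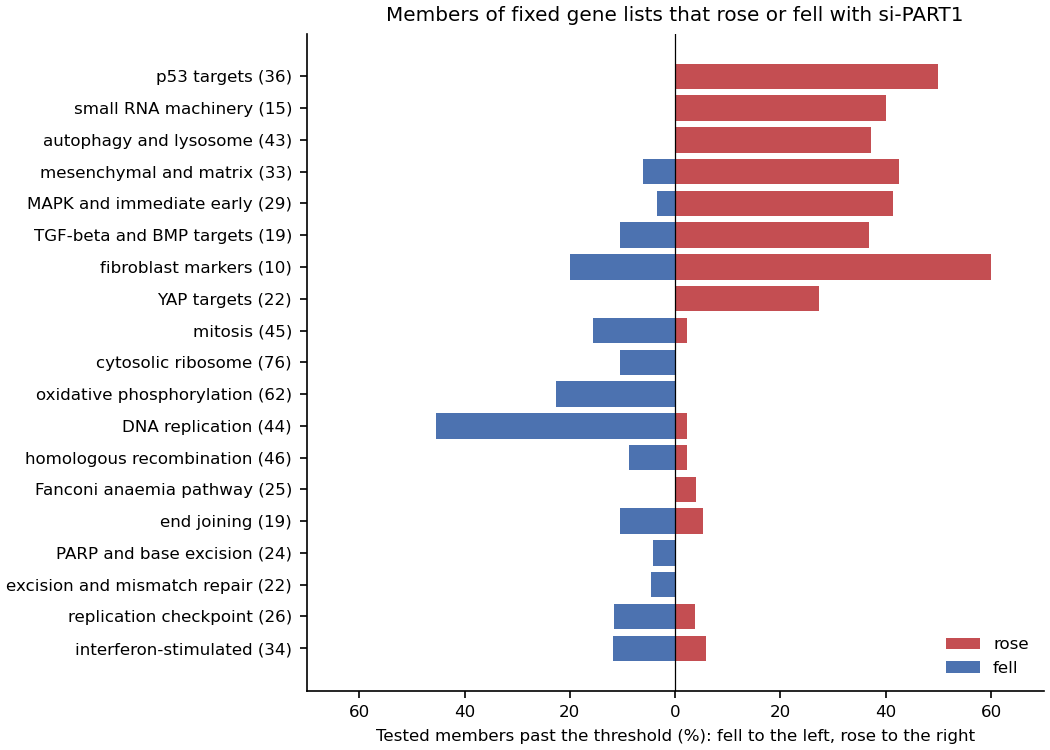
Percent of the tested members of 19 fixed gene lists that rose (red, to the right) or fell (blue, to the left) with si-PART1, with the number of tested members in brackets; both sides start at 0. p53 targets (18 of 36 higher) and DNA replication genes (20 of 44 lower) stand out, and the repair lists in the lower part have few members past the threshold.

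Other lists moved in both directions. Of 31 genes of the NRF2 response and ferroptosis 6 rose and 2 fell (7 and 5 adjusted over the list alone): GCLM and PGD fell, while HMOX1, which degrades haem, rose 1.83-fold, from 67.4 ± 8.39 to 123 ± 6.07 CPM (SD, n = 3 each). PGD, named after its values were seen, did not pass without si-NC library 3 (adjusted p = 0.122), and 5 members fell without si-PART1 library 3 or with the replicate block, and 4 with upper-quartile scaling or DESeq2. Of 42 genes of the unfolded protein and integrated stress responses 5 rose and 12 fell (7 and 13 adjusted over the list alone), with the transcription factor CEBPB at 59.7% of its si-NC level and the chaperone DNAJB9 1.59-fold higher. The 5 that rose were DNAJB9, SEL1L and, named after their values were seen, SESN2, HYOU1 and PPP1R15A. SESN2 lost its call without si-NC library 3 or si-PART1 library 2 (adjusted p = 0.0561 and 0.0614), HYOU1 without any library but si-PART1 library 3 (0.0710 to 0.131), and PPP1R15A without any but si-NC library 2 and si-PART1 library 3 (0.0781 to 0.198). With upper-quartile scaling HYOU1 and PPP1R15A did not pass (adjusted p = 0.0653 and 0.0560) and 3 members rose, against 8 with the replicate block or the GC and length correction. Between 6 and 7 members of this list fell without si-NC libraries 1, 2 or 3 or si-PART1 library 2. Of 29 genes of the BCL2 family and apoptosis 4 rose and 2 fell (the same counts adjusted over the list alone), with MCL1 (0.20), CASP9 (0.38) and BBC3 (0.33), the last 2 named after their values were seen, higher and CYCS (-0.25) and FADD (-0.49) lower. CYCS did not pass without si-PART1 library 2 (adjusted p = 0.0660), FADD without si-NC library 2 (0.102), CASP9 without si-NC libraries 2 or 3 or si-PART1 library 2 (0.0550 to 0.0684), and BBC3 without si-NC libraries 1 or 3 or si-PART1 libraries 1 or 2 (0.0745 to 0.0952). None of these 3 lists passed camera, with adjusted p from 0.480 to 0.543. In total 12 of the 38 tested lists passed with the preset correlation, 8 upward and 4 downward, and 3 of the 12 held with an estimated correlation: p53 targets, the small RNA machinery, and autophagy and lysosome.

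Markers of other cell types were low, apart from fibroblast markers. COL3A1 stood at 1738 ± 34.2 CPM in si-NC and 1962 ± 36.8 CPM in si-PART1 (SD, n = 3 each), POSTN at 658 and 772 CPM, and LUM at 282 and 333 CPM. Of 10 tested fibroblast markers 6 rose and 2, again THY1 and COL1A1, fell (the same counts adjusted over the list alone), and 6 of the list's genes also belong to the mesenchymal and matrix list. The fibroblast list passed camera with the preset correlation (adjusted p = 0.0314), with adjusted p = 0.358 with an estimated correlation, and did not pass with upper-quartile scaling (0.0539), with the stricter filter (0.0523), or without si-NC library 3 (0.0548) or si-PART1 library 1 (0.0525). Of 4 tested leukocyte markers CORO1A, at 4.90 and 2.21 CPM, fell. EGFL7, at 23.1 and 20.5 CPM, was the most abundant of 3 endothelial markers, and SFN, at 4.45 and 4.68 CPM, the higher of 2 squamous markers. HOXA9, at 24.9 and 32.5 CPM, was the 1 that rose of 4 mesothelial and ovarian markers, and no hepatocyte marker was tested.

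Of the 11 tested genes around PART1 on chromosome 5, PDE4D passed (1 adjusted over the list alone). PDE4D, a cyclic AMP phosphodiesterase (ENSG00000113448, chromosome 5, 58969038 to 60522120, minus strand), rose from 136 ± 3.39 to 159 ± 4.48 CPM (SD, n = 3 each), a log2 fold change of 0.23 ± 0.05 (SE, edgeR adjusted p = 0.00193). PART1 spans 60487713 to 60547657 on the plus strand in GENCODE 29 (hg38), so the ends of both genes overlap, and 227 exon bases of PDE4D, 1.39% of its exon bases, are shared with PART1. Reads of the shared bases cannot be assigned where counting ignored strand. The next of the listed genes beyond PART1, DEPDC1B, had a log2 fold change of 0.06 ± 0.07 (SE), and the repair gene ERCC8 had -0.25 ± 0.09 (SE, edgeR adjusted p = 0.0842). PLK2 had 0.44 ± 0.18 (SE, edgeR adjusted p = 0.105) and passed without si-NC library 3 (0.65, adjusted p = 0.0301).

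**Figure D5:**
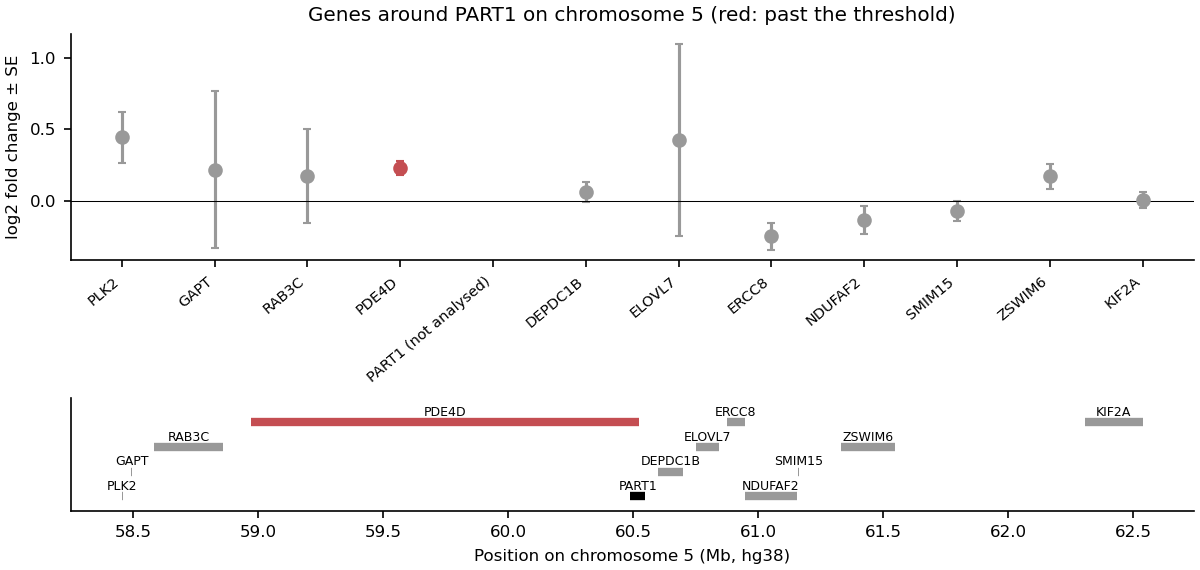
Upper panel: log2 fold change (si-PART1 over si-NC) with its SE for the tested genes around PART1, in order along chromosome 5. Lower panel: span of each gene in Mb (hg38); PDE4D, in red, is the 1 gene past the threshold (0.23 ± 0.05), and PART1, in black, was not analysed.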

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

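The correction for GC content and length without the block was chosen after the data were seen. Upper-quartile scaling moved the median log2 fold change of the tested genes by -0.0229, and RLE scaling by 0.00158. RLE scaling, no filter, the stricter filter and limma-voom each gave between 1175 and 1331 genes that rose and between 970 and 1045 that fell. DESeq2 gave 1375 and 1097, but only 47 rises and 45 falls of at least 2-fold, against 74 and 70. It gave an adjusted p to 13755 genes, against 18196 in the main fit. Whether the genes left out account for the fewer 2-fold changes was not tested. With GC content and length corrected, 1399 rose and 1102 fell. All 20 genes named for the size of their change passed in each of the 15 fits, while 44 of the 132 named list members gained or lost a call in at least 1. Leaving out 1 library left 2 against 3, and between 809 and 1383 genes rose, between 612 and 1121 fell, between 43 and 90 fell at least 2-fold, and 1 or 2 neighbours of PART1 passed. The lowest of these counts came without si-NC library 3 (809 rose, 619 fell) and without si-NC library 2 (612 fell, 43 at least 2-fold), which follow in part from the smaller group, while the highest came without si-PART1 library 3. The extra neighbour was PLK2, without si-NC library 3; the cause was not tested.

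With an estimated correlation 3 of the 12 gene lists passed, and why fewer passed than with the preset correlation was not tested on these lists. In the simulation, where genes were drawn independently, the shifted list also weakened. Its camera adjusted p was 2.995e-16 with the preset correlation and 0.0115 with an estimated one. A list that passed only with the preset correlation is therefore not shown to have members that vary together. Over the 15 fits 9 of the 12 lists passed throughout with the preset correlation, and fry passed 9 lists. By fry, which does not compare a list with other genes, the ribosome, mitosis, oxidative phosphorylation and YAP lists did not pass (adjusted p = 0.272, 0.0578, 0.134 and 0.124) and the leukocyte list did (0.0479).

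The replicate numbers showed no clear pairing of the libraries: deviations of same-numbered libraries from their group means correlated at 0.00726, 0.0162 and 0.0118. With the number as a block 1527 genes rose and 1303 fell, and with the block plus the correction for GC content and length 1441 and 1134. The fit without mitochondrially encoded genes and the value of PART1 were not run, as those genes were not analysed here. In the simulated comparison of 18024 genes, edgeR found 65 of 100 changes of 0.5 on the log2 scale, so changes of that size or less in genes with few counts can be missed at this depth.

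Of the 10 splits of the 6 libraries into groups of 3, the real one gave 2236 genes and the highest of the others 0. That other split count was also 0 with limma-voom, and at an unadjusted p under 0.05 the other splits gave between 353 and 889 genes, against 4376. In 1 of 10 splits a count as large was seen, the real one, and 10 splits are too few for a share under 0.05.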

Other observations

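The word scan, the 2 lists of REST targets and brain markers, the comparisons of TCGTCAT and GCACTTT with words of the same letters, the leaving out of words that overlap GCACTTT, the test of GCACTTT without TGCACTT, that of microRNA families without miR-92, and the comparison of PART1 with other long non-coding genes, were chosen after the genes that changed were seen. Genes that rose and fell differed in their 3' UTRs, with a median length of 2174 bases for genes that rose, 1073 for genes that fell and 1401 for the 11031 scanned genes. Of the 36 genes with TCGTCATA in the 3' UTR 44.4% fell. The share was 25.8% for the other 213 genes with TCGTCAT, 24.2% for 91 further genes with CGTCATA, 11% for 529 with CGTCAT alone and 6.98% for the 10162 with none of these. SLC7A2, GCLM and MRPL36, among the largest falls, hold TCGTCAT in the 3' UTR. Of the other large falls, ATP2A3 holds CGTCAT in the 3' UTR, and EIF2D, SRSF12, SLC5A6 and PPIP5K2 hold it in the coding sequence. Among the largest rises, AP3B2 holds CGTCAT in the 3' UTR, and BSN, CPLX1 and DISP2 hold it in the coding sequence. Genes with TCGTCAT were 71 of the 860 scanned genes that fell (8.26%), so most genes that fell lack it.

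REST, a repressor of neuronal genes in other tissues, was named after its values were seen. It went from 98.8 ± 4.22 to 58.2 ± 0.867 CPM (SD, n = 3 each), a log2 fold change of -0.76 ± 0.06 (SE, edgeR adjusted p = 4.95e-11). In a list of known REST targets written without the genes already seen to rise, 9 of 31 tested members rose and 1, RAB3A, fell (11 and 1 adjusted over the list alone); without si-NC library 3 the adjusted p of RAB3A was 0.144, and it also missed 0.05 without si-NC library 2 and si-PART1 libraries 1 and 2 (0.0520 to 0.0720). The members named here were chosen after their values were seen. CHGB went from 0.805 to 6.48 CPM, SYN1 from 1.42 to 4.17 CPM and NEFH from 135 to 230 CPM, while BDNF stood at 3.49 and 3.41 CPM.

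Genes with TCGTCAT in their 3' UTRs fell more often than others, 28.5% against 7.32%, and of all words scored this one had the lowest adjusted z. A place below other words therefore followed from how the word was picked, and picking also widens the gap to words that were not picked. Its z was -8.81, and the lowest of 119 other words of the same letters with a CG was -4.16 (SD 1.22). In the whole scan, the lowest word that shares fewer than 4 bases in a row with it was AAGCGAT, at -5.04. The SD of z over all words was 1.21. This second gap sets the word against the lowest of the scan, and it argues against composition or length of the 3' UTR as the whole cause. Genes with the word in the 3' UTR alone lay below genes with it in the coding sequence alone. The adjusted log2 fold change differed by -0.055 ± 0.019 (SE, 232 and 559 genes, one-sided permutation p = 0.00865). Pairing of a short RNA seed, as of an siRNA guide, with the 3' UTR predicts that direction. But the word was picked for its 3' UTR difference, which pushes this comparison the same way, so the comparison cannot decide. Genes with the word in the coding sequence alone were also lower than genes without it (-0.086 ± 0.010, SE), and 17.5% of them fell. The 5616-base transcript PART1-201 holds the word in exon 2 (chromosome 5, 60521048 to 60521054, hg38), which may be chance, since 6.55% of 397 long non-coding genes of similar length hold it too. The siRNA sequence is not given in the sources used here, so what part of the falls followed loss of PART1 and what part such pairing stays open.

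Some neuronal genes known as REST targets rose while REST fell: in the list, 9 of 31 tested members rose, 1 fell and 21 did not pass. RNA from brain cells is argued against, since 1 of 11 tested brain markers rose (MBP, adjusted p = 0.0516 without si-PART1 library 1). The most abundant, CNP, stood at 158 CPM in si-NC and 154 CPM in si-PART1. At that level in si-NC it would not show a trace of brain RNA. The markers under 1 CPM in si-NC did not pass: CAMK2A (0.72 CPM in si-NC and 0.43 in si-PART1), GFAP (0.46 and 0.48), RBFOX3 (0.46 and 0.30) and SOX10 (0.32 and 0.36). Release of REST targets is a candidate explanation: the list written without the genes already seen had a median of 0.31 on the log2 scale (camera p = 2.05e-08, and p = 0.00538 with an estimated correlation). Only 31 of its 58 members were tested. A target silent in si-NC could enter the test through si-PART1 alone, as did SCG3 (0.0611 CPM in si-NC), while targets silent in both groups dropped out. This filter can raise the median and the share that rose. The 3' UTR of REST, of 3692 bases, holds TCGTCATA once, from base 561, but whether REST fell through that site or through loss of PART1 was not tested.

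Genes that rose often carry GCACTTT, the site of the miR-17 family, in their 3' UTRs: 18% of 2852 genes with it rose, against 7.96% of those without. Its adjusted z was 6.88, and the highest of 371 other words of the same letters that share fewer than 4 bases in a row with it was 3.49 (SD 1.18). Of words that share 4 or more, TGCACTT (7.86) and TTTGCAC (7.56) lay above it, and among 9186 genes without TGCACTT its z was 2.46, so the signal is not specific to GCACTTT. GCACTTT was itself among the 10 highest words of the scan, and 2.46 lies below 3.49. These comparisons therefore cannot decide whether composition or length of the 3' UTR is the cause. Relief of repression by broadly expressed microRNAs stays open: sites of 12 broadly expressed families, chosen without miR-17, miR-19 and miR-130, had a mean adjusted z above that of 12 tissue-restricted families by 2.31 (one-sided permutation p = 0.0001), and by 2.09 without miR-92, whose word GTGCAAT was among the 10 highest of the scan (p = 0.00019). Loss of PART1 itself stays among the open explanations, untested.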
